A study of Mus musculus with 4 samples.

How the data were processed

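The study measured poly(A) RNA in whole mouse embryos at the 2-cell stage by RNA sequencing of pre-amplified cDNA. Zygotes had been injected with a control small interfering RNA (siRNA) or with an siRNA against SPENH0335, each at 20 μM per the labels' protocols, and then cultured in KSOM, an embryo culture medium. SPENH0335 is taken from the series' title to be an RNA made from an enhancer. The 4 libraries form 2 groups of 2, called control and knockdown here. How many embryos went into a library, and whether the libraries came from separate collections of zygotes, is not given in the sources used here. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. List tests with a preset correlation set a list's genes against the other genes, so their p-values rest on the spread between genes. The permutation p of neighbouring genes rests on permuted gene orders.

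The deposited table holds whole-number counts per gene, by their values not normalized by the authors, with 53715 rows named by versioned Ensembl gene IDs and 1 column per library. The submitters' processing notes name CASAVA 1.8, Trim Galore 0.6.5, HISAT2 2.1.0, Picard 2.18.2 and the genome build mm10, without saying what each was used for. The counting tool, the annotation release, the strand setting, the treatment of duplicate reads and whether reads or fragments were counted are not given in the sources used here. Without a known strand setting, reads from overlapping and antisense genes cannot be told apart, and counts of near-identical gene copies depend on how shared reads were assigned. The cDNA was pre-amplified and the labels name no molecular identifiers, so floors cover counting error only.

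Gene symbols, biotypes and coordinates were taken from GENCODE release M21 on GRCm38, the assembly that mm10 also names. By Ensembl ID without version, 53620 rows matched, 51464 of them with the same version. The 95 unmatched rows held at most 0.0164% of a library's counts and stayed in the test. No row was named for SPENH0335, and its genomic position is not given in the sources used here.

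Total counts per library were 87900405 and 78865491 in control and 94257563 and 99011109 in knockdown. Counts of each pair of libraries were compared to look for a library deposited more than once. The closest pair, the control replicates, had a chi-square of 30.9 per degree of freedom, so no pair was counted as 1 sample. This does not show that the libraries came from separate embryos.

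Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum of 10 counts, which left 25565 genes, libraries were scaled by the trimmed mean of M-values (TMM), and the quasi-likelihood F-test compared knockdown with control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Group was the only term of the model. Expression is given as TMM-scaled CPM (counts per library scaled to a common total), as the mean ± SD of the 2 libraries of a group. Fold changes are knockdown over control on the log2 scale. Their standard error (SE) is the fold change divided by the square root of F, and 95% intervals use the t distribution with the test's degrees of freedom. For a gene with no counts in a group, a lower bound of the fold was computed against a floor of 3 counts over that group, which covers counting error only.

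Lists of genes were fixed before the data were examined: genes transcribed transiently at the 2-cell stage, Obox factors, maternal oocyte transcripts, maternal mRNA decay, ribosome biogenesis, cytosolic ribosomal proteins, translation initiation, splicing, proteasome, oxidative phosphorylation, the mitochondrial genome, G2 and mitosis, DNA replication, p53 targets, interferon response, protein folding and oxidative stress, lineage and pluripotency, chromatin modifiers, transcription machinery, glycolysis, cholesterol synthesis and apoptosis, with cumulus and granulosa, sperm, and blood, oviduct and stroma markers as checks for other cell types. They were tested with camera from limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 25 lists. The rule for naming genes, also fixed beforehand, took the 10 largest changes in each direction among genes past the threshold with groups that did not overlap and a mean of at least 10 CPM, leaving out symbols that only number a gene model, clone or pseudogene. Where fewer passed, it took the genes with the smallest p up to 5 in each direction, whatever their symbol, and this part applied here. It added the members of each list with the smallest p, up to 4 past the threshold or 2 in a list with none, and a panel of 10 genes whatever their result.

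The test was checked on simulated data drawn from the means, library sizes and gene-wise dispersions of these libraries, with 200 genes changed. At a mean of at least 10 CPM it called 16 of 35 genes changed by 2-fold, 36 of 40 changed by 4-fold and 31 of 31 changed by 8-fold. At 1 to 10 CPM it called 0 of 32, 7 of 27 and 21 of 35. It also called 11 unchanged genes. The 200 changed genes ease the adjusted threshold, so these shares need not hold in the real libraries. There Gm2117, at 14.9 CPM in control and 62.2 CPM in knockdown, was not called (edgeR adjusted p 0.9999). A shift of all ribosomal protein genes by -0.5 on the log2 scale gave a camera adjusted p of 4.26e-09, and no other list was called. Genes were drawn independently there, while the estimated correlation of this list was 0.72 in the real libraries, so this does not show that such a shift would be called in them.

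Alternatives fixed beforehand were median-ratio (RLE) size factors, library totals alone, no filter beyond 1 count, a minimum mean of 10 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, a within-library correction for transcript length and GC content with and without that block, leaving out each library, a minimum log2 fold change of 1, a threshold of 0.01, and leaving out mitochondrial and the 10 most abundant genes. For the lists they also included camera with an estimated correlation and the fry rotation test. With an estimated correlation camera uses only the residual degrees of freedom of these few libraries, so almost no list could pass it.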

Results

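The transcriptome of 2-cell mouse embryos was compared between 2 control libraries and 2 libraries from embryos injected as zygotes with an siRNA against SPENH0335, taken from the series' title to be an RNA made from an enhancer. The embryos were of a C57BL/DBA2 background. Libraries held between 78865491 and 99011109 counts and between 29472 and 29876 genes with at least 1 count. Protein-coding genes took 91.2 to 91.7% of the counts. All means below are over 2 libraries per group.

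The only comparison the design names asks what changes in embryonic gene expression when SPENH0335 is knocked down. The target itself could not be read from the gene table, which has no row for it, so the size of the knockdown was not measured here.

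No gene was higher or lower in knockdown embryos than in controls at an adjusted p under 0.05 (edgeR quasi-likelihood test, 25565 genes, smallest adjusted p 0.595). At an unadjusted p under 0.05 there were 399 genes higher and 585 lower, together 3.85% of the genes, against 4.88% of the unchanged genes in simulated data. DESeq2, run on 36863 genes without the low-count filter, called 19 genes higher and 32 lower at an adjusted p under 0.05. With limma-voom 0 were called, with 799 genes at an unadjusted p under 0.05. Without knockdown replicate 1, edgeR called 2 genes higher and 1 lower, and without knockdown replicate 2 it called 1 higher and 1 lower. The groups did not overlap for 32.7% of the genes, against 33.3% by chance for 2 libraries against 2.

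Of the 8185 genes with a mean of at least 10 CPM, 7184 had a 95% interval that lay within 2-fold in either direction. For genes over 100 CPM, the median absolute log2 difference was 0.19 between the knockdown replicates and 0.07 between the control replicates. Between the group means, each over 2 libraries, it was 0.10. Averaging lowers the part of a difference that comes from spread between libraries. The value for the means therefore cannot be read directly against those for single libraries. The first principal component, with 38.5% of the variance, set the knockdown libraries at opposite ends, and the second, with 32.6%, separated knockdown from control. The third and last held 28.9%, so the shares were close to even. Log2 CPM correlated at 0.914 between the knockdown replicates and 0.93 between the control replicates. Between libraries of different groups the correlation ran from 0.92 to 0.924.

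**Figure D1:**
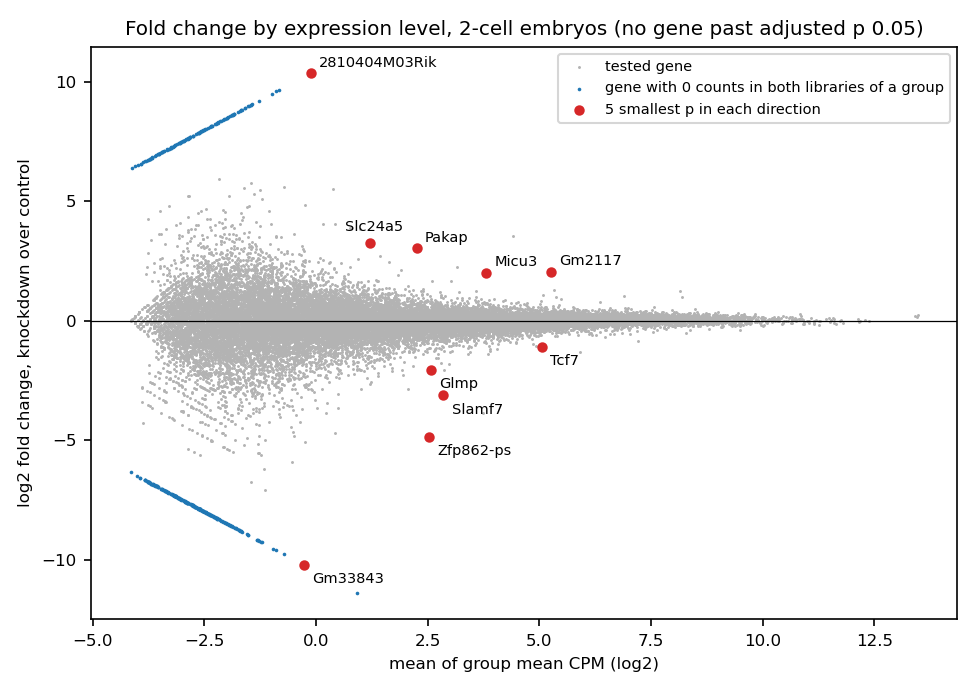
Log2 fold change of knockdown over control (vertical axis) against the mean of the group mean CPM on a log2 scale (horizontal axis) for the 25565 tested genes. Red points are the 5 genes with the smallest p in each direction, blue points are genes with no counts in both libraries of a group, whose plotted fold changes depend on the prior count, and no gene passed an adjusted p of 0.05.

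Among the genes with the smallest p, the lowest p belonged to Zfp862-ps, a transcribed unitary pseudogene on chromosome 6 (48504337 to 48534832, GRCm38). It was at 11.2 ± 1.79 CPM in control and 0.388 ± 0.0518 CPM in knockdown, a log2 fold change of -4.85 (SE 0.37, adjusted p 0.595). Slamf7, a receptor of the signalling lymphocyte family on chromosome 1 (171632403 to 171653035), was at 12.9 ± 1.43 CPM in control and 1.49 ± 0.751 CPM in knockdown. Glmp, a lysosomal membrane glycoprotein gene on chromosome 3 (88325023 to 88331313), was at 9.54 ± 0.675 and 2.31 ± 0.0451 CPM. Tcf7, which encodes the Wnt pathway transcription factor TCF-1 on chromosome 11 (52252371 to 52283014), was at 45.3 ± 2.94 and 21.4 ± 1.56 CPM, a log2 fold change of -1.09 (SE 0.17). The long noncoding RNA gene Gm33843 on chromosome 10 (96519157 to 96595731) had 131 and 146 counts in the control libraries and 0 in both knockdown libraries, at least 104-fold lower against a floor of 3 counts.

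In the other direction, Gm2117, a long noncoding RNA gene on chromosome X (28005050 to 28047399), was at 14.9 ± 0.0368 CPM in control and 62.2 ± 12.3 CPM in knockdown, a log2 fold change of 2.06 (SE 0.20). Micu3, a regulator of the mitochondrial calcium uniporter on chromosome 8 (40307458 to 40386308), was at 5.57 ± 0.774 and 22.4 ± 1.03 CPM, a log2 fold change of 2.01 (SE 0.24). Pakap on chromosome 4 (57568179 to 57896982) was at 1.04 ± 0.449 and 8.48 ± 2.57 CPM. Slc24a5, a cation exchanger of pigment cells on chromosome 2 (125068124 to 125088677), was at 0.437 ± 0.195 and 4.15 ± 0.0898 CPM. The long noncoding RNA gene 2810404M03Rik on chromosome 8 (41827267 to 42046202) had 0 counts in both control libraries and 156 and 194 in the knockdown libraries, at least 103-fold higher against the same floor. None of these passed the edgeR test (adjusted p 0.9999 for each gene but Zfp862-ps), and DESeq2 called all 10. In each of the 10, both knockdown libraries lay on the same side of both control libraries, which their choice by the smallest p makes likely and which is no further support.

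None of the 25 gene lists passed the test (camera, smallest adjusted p 0.327, and 0.90 with an estimated correlation). In camera, 1 list had an unadjusted p under 0.05. For a shared direction fry called 0 lists (smallest fry adjusted p 0.758). For members changed in mixed directions the smallest fry adjusted p was 0.0516, for apoptosis, which did not pass. No member of any list passed over all genes, and 0 passed adjusted over the list alone, while up to 4 members of a list had an unadjusted p under 0.05. Requiring a mean of at least 10 CPM called 3 lists, and leaving out control replicate 1, knockdown replicate 1 or knockdown replicate 2 called 1 list each; none of these calls held with an estimated correlation. With so few residual degrees of freedom almost no list could pass with an estimated correlation, so failing there says little by itself. The calls, however, rest on the preset correlation of 0.01. The estimates over all libraries were 0.72 for ribosomal proteins, 0.41 for maternal transcripts and 0.029 for the proteasome. For the ribosomal and maternal lists the preset thus treats correlated genes as nearly independent, which makes a call too easy. The direction of uncalled lists turned without control replicate 2 for Obox factors, translation initiation, oxidative phosphorylation, the mitochondrial genome, lineage factors and cumulus markers. It turned without knockdown replicate 1 for 2-cell genes, Obox factors, maternal transcripts, translation initiation, the proteasome, the mitochondrial genome and DNA replication. It turned without knockdown replicate 2 for mRNA decay, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, G2 and mitosis, lineage factors and apoptosis.

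**Figure D2:**
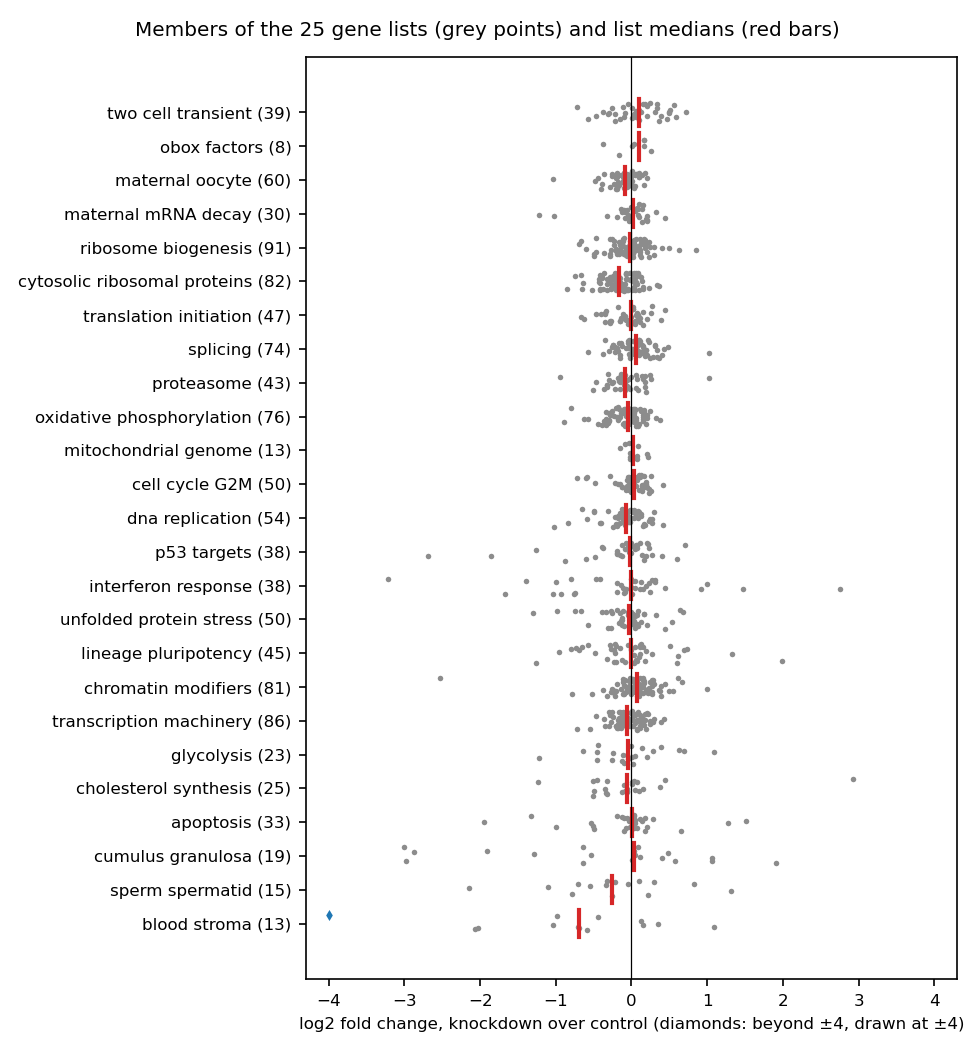
Log2 fold change of knockdown over control (horizontal axis) for every tested member of the 25 gene lists (rows, with the number of tested members). Grey points are genes, red bars are list medians, and the blue diamond is a gene below -4 drawn at -4; the list medians lie between -0.69 and 0.10.

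The genes transcribed transiently at the 2-cell stage, which mark the first large wave of embryonic transcription, summed over 39 tested members to 2414 ± 31.8 CPM in control and 2607 ± 119 CPM in knockdown, with a median log2 fold change of 0.09 (camera adjusted p 0.738) and 25 members above 0; without knockdown replicate 1 the list's direction was down (adjusted p 0.934). The member with the smallest p was Zscan4f, of the Zscan4 zinc finger family of this stage, at 152 ± 7.45 and 225 ± 19.3 CPM (log2 fold change 0.56, SE 0.12). Zscan4d was at 140 ± 1.70 and 180 ± 4.49 CPM. Arg2, a mitochondrial arginase, was at 122 ± 18.2 in control and 82.0 ± 4.34 CPM in knockdown. Zfp352 was at 244 ± 11 and 270 ± 13.9 CPM, and Duxf3, an upstream activator of this program, at 2.39 ± 0.318 and 2.55 ± 0.547 CPM. Zscan4, Tdpoz and Usp17l genes are near-identical copies, so values of single members are uncertain. The 8 Obox homeobox factors had a median log2 fold change of 0.10 (camera adjusted p 0.776), with Obox1 at 952 ± 26.8 and 1067 ± 185 CPM and Obox7 at 297 ± 8.65 and 333 ± 65.1 CPM.

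Maternal oocyte transcripts, inherited from the egg and degraded around this stage, summed to 54573 ± 18.5 CPM in control and 54093 ± 5336 CPM in knockdown. Of 60 members, 41 had a fold change below 0, with a median of -0.08 (camera adjusted p 0.738). Gdf9, an oocyte growth factor, was at 378 ± 13.0 and 286 ± 18.4 CPM (log2 fold change -0.40, SE 0.10), and Nlrp14 was at 821 ± 102 and 629 ± 50.6 CPM. Dppa3, a maternal protector of DNA methylation, was at 1909 ± 126 and 1952 ± 5.36 CPM, and Zp3, a zona pellucida protein gene, at 39.4 ± 0.0218 and 39.3 ± 2.08 CPM. The list was called lower at a mean of at least 10 CPM (adjusted p 0.00623; adjusted p = 0.868 with an estimated correlation) and without knockdown replicate 2 (adjusted p 0.000569; adjusted p = 0.97 with an estimated correlation), and took the other direction without knockdown replicate 1 (adjusted p 0.359). Over all alternatives its adjusted p ran from 0.000569 to 0.99. Of the 30 maternal mRNA decay factors, 15 lay above and 15 below 0, with a median of 0.02 and a mean of -0.03 (camera adjusted p 0.798, direction up; fry direction down). Cnot6, a deadenylase subunit, was at 73.6 ± 3.01 and 99.7 ± 2.55 CPM, and Dis3l2, an exonuclease of uridylated RNA, at 6.82 ± 1.30 and 2.92 ± 0.188 CPM.

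Of the 82 cytosolic ribosomal protein genes, 62 had a fold change below 0, with a median of -0.16 (camera adjusted p 0.327; adjusted p = 0.90 with an estimated correlation). Their sum was 2801 ± 320 CPM in control and 2555 ± 582 CPM in knockdown, with the lowest sum, 2143 CPM, in knockdown replicate 2 and 2966 CPM in knockdown replicate 1. The list was called lower without knockdown replicate 1 (adjusted p 1.28e-07; adjusted p = 0.878 with an estimated correlation), without control replicate 1 (0.0422; adjusted p = 0.954 with an estimated correlation) and at a mean of at least 10 CPM (0.000609; adjusted p = 0.868 with an estimated correlation), and took the other direction without knockdown replicate 2 (adjusted p 0.27). Over all alternatives its adjusted p ran from 1.28e-07 to 0.996. Rpl10 was at 75.5 ± 3.43 and 56.7 ± 7.95 CPM and Rps2 at 87.5 ± 6.03 and 69.8 ± 2.65 CPM, both of families with many processed pseudogenes that can share their reads. The 43 proteasome subunits had a median of -0.09 (camera adjusted p 0.773) and were called lower at a mean of at least 10 CPM (0.0353, in a range up to 0.996 over all alternatives; adjusted p = 0.868 with an estimated correlation), while without knockdown replicate 1 their direction was the other (adjusted p 0.934). Psma1 was at 94.9 ± 2.25 and 68.3 ± 6.06 CPM and Psmd7 at 45.5 ± 0.632 and 32.0 ± 3.73 CPM. Ribosome biogenesis factors, whose transcription begins at the 2-cell stage, had a median of -0.02 over 91 genes (camera adjusted p 0.776), with Nmd3 at 135 ± 4.98 and 95.6 ± 3.56 CPM and Utp4 at 51.8 ± 1.39 and 37.6 ± 0.433 CPM. The translation initiation list, which also holds the elongation factor gene Eef2, had a median of -0.01 over 47 genes (camera adjusted p 0.776). Eif5a was at 584 ± 10.3 and 483 ± 0.495 CPM, Eef2 at 24.5 ± 0.453 and 33.4 ± 3.27 CPM, and Eif1a at 32.8 ± 2.98 and 30.9 ± 18.5 CPM.

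Transcription machinery genes had a median of -0.05 over 86 genes (camera adjusted p 0.776), with Taf5, a subunit of TFIID, at 88.8 ± 5.82 and 120 ± 24.4 CPM and Nelfb at 4.03 ± 0.363 and 2.44 ± 0.0178 CPM. Splicing factors had a median of 0.06 over 74 genes (camera adjusted p 0.773), with Srsf2 at 49.1 ± 8.29 and 66.1 ± 1.34 CPM and Hnrnpu at 164 ± 15.4 and 200 ± 14 CPM. Chromatin modifiers had a median of 0.08 over 81 genes, 52 of them above 0 (camera adjusted p 0.738). Smarca5, an ISWI remodelling ATPase, was at 226 ± 9.16 and 292 ± 18.9 CPM, and Trim28, a corepressor of transposable elements, at 30.0 ± 2.24 and 42.2 ± 5.08 CPM. Among lineage and pluripotency factors the median was -0.0033 over 45 genes (camera adjusted p 0.776). Pou5f1 was at 20.1 ± 2.08 and 18.9 ± 0.715 CPM, Nanog at 0.328 ± 0.0942 and 1.31 ± 1.07 CPM, Krt18 at 9.94 ± 2.59 and 5.72 ± 1.05 CPM and Zfp42 at 19.4 ± 3.88 and 12 ± 3.70 CPM.

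**Figure D3:**
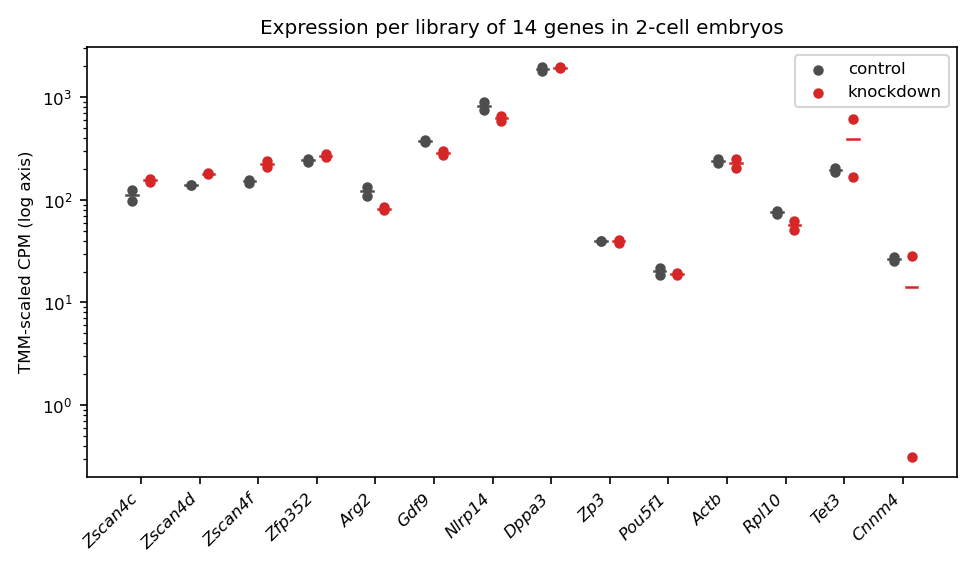
TMM-scaled CPM on a log axis for 14 genes (horizontal axis) in each library; points are libraries (grey control, red knockdown) and short lines are group means over 2 libraries. Zscan4f is at 152 CPM in control and 225 CPM in knockdown on average, while Tet3 and Cnnm4, which like Zscan4c were added after their values were seen, each have a single knockdown library apart from the other libraries.

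No list of energy metabolism passed the test. Oxidative phosphorylation subunits had a median of -0.04 over 76 genes (camera adjusted p 0.776), with Ndufb2 at 26.8 ± 0.985 and 34.8 ± 3.14 CPM and Cox8a at 178 ± 13.0 and 143 ± 25.4 CPM. The 13 protein genes of the mitochondrial genome summed to 36499 ± 2343 CPM in control and 38077 ± 3296 CPM in knockdown (camera adjusted p 0.776), with mt-Atp6 at 10145 ± 230 and 11738 ± 799 CPM and mt-Atp8 at 1720 ± 7.52 and 2000 ± 233 CPM. Glycolysis genes had a median of -0.05 over 23 genes (camera adjusted p 0.776), with Hk2 at 10.6 ± 2.16 and 17.1 ± 7.42 CPM and Ldha at 7.66 ± 0.327 and 5.60 ± 0.195 CPM. Cholesterol synthesis genes had a median of -0.06 over 25 genes (camera adjusted p 0.776), with Lss, lanosterol synthase, at 3.95 ± 0.678 and 1.67 ± 0.137 CPM and Hsd17b7 at 66.6 ± 0.965 and 52.4 ± 12.1 CPM.

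No list of the cell cycle or of stress passed the test. Genes of G2 and mitosis had a median of 0.04 over 50 genes (camera adjusted p 0.776), with Fbxo5, an inhibitor of the anaphase-promoting complex, at 86.6 ± 2.09 and 57.8 ± 6.84 CPM and Mki67 at 404 ± 25 and 485 ± 27.9 CPM. DNA replication genes had a median of -0.07 over 54 genes (camera adjusted p 0.776), with Orc5 at 599 ± 34.4 and 514 ± 14.3 CPM and Rfc2 at 6.36 ± 2.38 and 3.11 ± 1.03 CPM. The p53 targets had a median of -0.02 over 38 genes (camera adjusted p 0.776), with Ccng1 at 28.8 ± 2.79 and 15.7 ± 3.32 CPM and Eda2r at 1.52 ± 0.274 and 0.235 ± 0.166 CPM. Apoptosis regulators had a median of 0.01 but a mean of -0.05 over 33 genes (camera adjusted p 0.776, direction down), with Bok at 1.81 ± 0.158 and 0.467 ± 0.00169 CPM and Bad at 2.39 ± 0.151 and 0.954 ± 0.731 CPM. The interferon response, which double-stranded RNA can induce, had a median of -0.01 over 38 genes (camera adjusted p 0.773) and summed to 353 ± 2.80 and 345 ± 0.283 CPM. Dhx58, a sensor of double-stranded RNA, was at 3.23 ± 0.226 and 1.01 ± 0.332 CPM, and Trim25 at 5.83 ± 0.0276 and 2.84 ± 0.346 CPM. Protein folding and oxidative stress genes had a median of -0.03 over 50 genes (camera adjusted p 0.776), with Srxn1 at 2.27 ± 0.844 and 0.915 ± 0.391 CPM and Hspb1 at 33.4 ± 0.361 and 21.1 ± 9.22 CPM. Actb, which encodes cytoplasmic actin, was at 240 ± 15.1 and 229 ± 31.8 CPM.

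No list of markers of other cell types passed the test. Cumulus and granulosa markers summed to 90.8 ± 6.67 CPM in control and 91.6 ± 7.89 CPM in knockdown (19 genes, median log2 fold change 0.03, mean -0.43, camera adjusted p 0.776, direction down), with Has2, the hyaluronan synthase of expanding cumulus cells, at 2.61 ± 0.0517 and 0.695 ± 0.335 CPM and Foxl2 at 0.993 ± 0.145 and 0.125 ± 0.146 CPM. Sperm markers summed to 199 ± 0.281 and 192 ± 5.47 CPM (15 genes, median -0.26, camera adjusted p 0.776), with Pgk2 at 2.27 ± 0.870 and 5.67 ± 3.53 CPM and Ldhc at 6.60 ± 1.37 and 4.04 ± 1.92 CPM. Blood, oviduct and stroma markers summed to 131 ± 11.6 and 114 ± 21.8 CPM (13 genes, median -0.69, camera adjusted p 0.738), with Krt7 at 1.61 ± 0.616 and 0.391 ± 0.275 CPM and Lyz2, a macrophage lysozyme, at 11.8 ± 10.8 and 2.81 ± 1.94 CPM. The control libraries were at 4.18 and 19.4 CPM for Lyz2, and its log2 fold change of -2.07 was -0.57 without control replicate 2 and -3.03 without knockdown replicate 1.

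Of the 69 genes taken by the naming rule and the panel, the log2 fold change of 29 moved by over 1.5 times or changed sign when a single library was left out. It changed sign for Actb, Dppa3, Duxf3, Eif1a, Obox1, Obox7, Pou5f1 and Zp3, and Lyz2 is given above. Without control replicate 1 it went from the value over all libraries to a smaller size for Nlrp14 (-0.38 to -0.26), Srsf2 (0.43 to 0.26) and Hnrnpu (0.29 to 0.19). Without control replicate 2 the same held for Rfc2 (-1.03 to -0.59), Srxn1 (-1.31 to -0.87) and Krt18 (-0.80 to -0.50). Without knockdown replicate 1 it moved for Foxl2 (-2.98 to -5.45), Pgk2 (1.32 to 0.48), Zfp352 (0.15 to 0.09) and Nanog (1.99 to 0.75), and without knockdown replicate 2 for Rpl10 (-0.41 to -0.27) and Taf5 (0.43 to 0.21). Without knockdown replicate 1 and without knockdown replicate 2, in this order, it moved for Cox8a (-0.50 and -0.14), mt-Atp8 (0.10 and 0.34), Hspb1 (-1.20 and -0.27) and Zfp42 (-1.05 and -0.40). The same order gave Hk2 (1.09 and 0.18), Hsd17b7 (-0.13 and -0.60), Bad (-2.45 and -0.69) and Ldhc (-1.30 and -0.28).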

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

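The combinations of another setting with an estimated correlation were chosen after seeing the data. The counts of called genes stayed at 0 in both directions under RLE size factors, library totals alone, no filter and a minimum of 10 CPM. They also stayed at 0 under limma-voom, the length and GC correction and the removal of abundant genes. A log2 fold change of at least 1 and the 0.01 threshold only narrow the main fit's calls, so they could give nothing but 0. DESeq2 called 19 higher and 32 lower. With a library left out the counts ranged from 0 to 2 higher and from 0 to 1 lower; a lone library is then assumed to vary like the other group. The replicate block gave 0 calls in both directions, with and without the length and GC correction, and 0 lists; the labels do not say what the replicate number marks, and the deviations of same-numbered libraries from the group means correlated at -0.019. The lists called were 0, but 3 at a minimum of 10 CPM and 0 to 1 with a library left out, and 0 in each of these with an estimated correlation. The cause was not tested. An estimated correlation leaves too few residual degrees of freedom for almost any list to pass, so the 0 there says little by itself. The calls rest on the preset correlation of 0.01, against estimates of 0.72 for ribosomal proteins and 0.41 for maternal transcripts. For these lists the preset makes a call too easy. Uncalled directions changed in 21 of 253 pairs of a list and a setting and in 17 of 937 pairs of a named gene and a setting. Maternal mRNA decay turned under fry (adjusted p 0.816). With a library left out, adjusted p ran from 0.359 to 0.996 for apoptosis, 0.121 to 0.996 for G2 and mitosis and for oxidative phosphorylation, 0.403 to 0.996 for cumulus and granulosa, 1.28e-07 to 0.996 for ribosomal proteins, 0.131 to 0.996 for DNA replication, 0.124 to 0.996 for lineage factors, 0.698 to 0.996 for mRNA decay, 0.000569 to 0.99 for maternal transcripts, 0.368 to 0.996 for the mitochondrial genome, 0.592 to 0.996 for Obox factors and translation initiation, 0.155 to 0.996 for the proteasome, 0.326 to 0.996 for ribosome biogenesis and 0.168 to 0.996 for 2-cell genes. With an estimated correlation the called lists had an adjusted p of 0.878 (ribosomal proteins, without knockdown replicate 1), 0.954 (ribosomal proteins, without control replicate 1) and 0.97 (maternal transcripts, without knockdown replicate 2). Log2 fold changes ran from -0.22 to 0.070 for Actb, -0.037 to 0.10 for Dppa3, -0.14 to 0.30 for Duxf3, -0.88 to 0.43 for Eif1a, -0.018 to 0.33 for Obox1, -0.045 to 0.35 for Obox7, -0.19 to 0.020 for Pou5f1 and -0.055 to 0.058 for Zp3. Zp3 was at 0.0070 under RLE, 0.012 in DESeq2 and 0.14 with the length and GC correction, with or without the block. Pou5f1 was at 0.066 with that correction and 0.071 with the block as well, and Dppa3 at -0.0083 under library totals. Below 1 CPM the median half-width of the 95% interval was 3.36 on the log2 scale.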

Other observations

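Of the tests below, those on the Zscan4 genes were chosen after the result was seen; the others were set before their results were known, except the interval of the length and GC test, which was chosen after. The genes of this paragraph are among the 10 with the highest mean CPM and were chosen after their values were seen. Spin1, a spindle protein gene of the oocyte, was at 10695 ± 236 CPM in control and 11744 ± 1504 CPM in knockdown. Tcl1, a cofactor of the AKT kinase, was at 3697 ± 37.2 and 3440 ± 118 CPM, and Oog3 at 3420.5 ± 16.3 and 3513 ± 408 CPM. Mdm4, an inhibitor of p53, was at 4395 ± 96.7 and 4655 ± 34.8 CPM. The pseudogene Gm10925 on chromosome 1 was at 10389 ± 262 and 12318 ± 1177 CPM, beside mt-Atp6 at 10145 ± 230 and 11738 ± 799 CPM.

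Several genes stood apart in a single knockdown library. They were chosen after their values were seen, as the only calls made by edgeR when a library was left out. Single deviating libraries also occurred in control: Clec4e had 437 counts in control replicate 2 and 0 in the other libraries. Tet3, the dioxygenase that oxidizes methylated cytosine in the zygote, was at 612 CPM in knockdown replicate 2 and at 167 to 203 CPM in the other libraries. Nav2, a neuron navigator gene, was at 630 CPM in the same library and at 161 to 178 CPM elsewhere, and the noncoding Gm2101 was at 13.8 CPM there and at 55.9 to 86.5 CPM elsewhere. In knockdown replicate 1, the magnesium transporter gene Cnnm4 was at 0.311 CPM against 25.4 to 28.1 CPM in the other libraries, and Gm42418 was at 76.0 CPM against 2.62 to 3.90 CPM. Left out of the fit in turn, knockdown replicate 1 gave adjusted p of 0.0133 for Tet3 and Nav2 and 0.0169 for Gm2101, and knockdown replicate 2 gave 0.0266 for Cnnm4 and Gm42418 (edgeR).

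The first pattern is that the 6 Zscan4 genes of the fixed list each had a positive log2 fold change, with a median of 0.48, also under RLE size factors (0.49), library totals alone (0.45) and without any single library (medians from 0.25, without knockdown replicate 1, to 0.67, without knockdown replicate 2). Their summed CPM was 498 and 537 in control and 768 and 657 in knockdown, a ratio of 1.38, and in 4 of the 6 both knockdown libraries lay above both control libraries. In these libraries the other 33 members of the 2-cell list had a median of 0.029 (bootstrap 95% interval -0.10 to 0.13, over genes as if independent). That interval holds no spread between libraries, and the Zscan4 genes were picked as higher members. The values therefore do not decide whether the whole list shifted. A single deviating knockdown library stays open: the lower knockdown library exceeded the higher control library by 121 CPM (differences of 39.1 CPM within control and 111 CPM within knockdown), but the family was picked because it was higher, and the 95% prediction bound from 2 controls, 947 CPM, lay above both knockdown libraries, so that test could not have excluded it. Shared reads, which may make the 6 genes a single observation, chance and an effect of the knockdown stay open too, and none of the genes passed the test.

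The second pattern is the negative median of the ribosomal protein genes. In knockdown replicate 2 the median log2 difference from the control mean was -0.51, in knockdown replicate 1 it was 0.122, and the control libraries differed by a median of 0.26. These values are consistent with a deviation of knockdown replicate 2 alone. With the length and GC correction the median went from -0.16 to -0.0984, a share of 0.61 kept against a limit of 0.5 set beforehand. Its 95% interval was 0.51 to 0.90, with the same genes drawn before and after, as if independent of each other. The estimated correlation of these genes was 0.72, so that interval is too narrow and cannot decide whether these properties were the main cause. An effect of the knockdown stays open as untested.

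The third pattern is that DESeq2 called 51 genes where edgeR called 0. DESeq2 ran with its own scaling on 36863 genes, without the filter that left 25565 genes for edgeR. Without that filter edgeR also called 0. The DESeq2 call Clec4e was not tested in the main edgeR fit. Of the 51, 21 had no counts in both libraries of a group and 50 had an unadjusted p under 0.05 in edgeR. Of the 3 ways to split the 4 libraries into pairs, 2 gave at least as many DESeq2 calls as the real one, itself included, and the highest other number was 54. Genes of at least 1 CPM with a 4-fold gap between all libraries of the groups numbered 18 in the real split and at most 16 in the others, so 1 of the 3 splits, the real one, reached that number. With 3 splits no share under 0.05 is possible.

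Because an enhancer RNA can act on genes near its locus, a further hypothesis was that neighbouring genes shifted together. Over 16100 genes of at least 1 CPM, the largest running mean of the test's z-scores over 5 neighbours was 1.72, against a median of 1.65 and a 95th percentile of 1.89 in 1000 permuted gene orders (permutation p 0.269 for a mean of either sign). That window held Tcl1b2, Tcl1b1, Tcl1b5, Tcl1b3 and Tcl1b4, related genes on chromosome 12 (105146014 to 105206993), with log2 fold changes from -0.22 to -0.13. The test found no such locus and does not exclude one.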
